A study of Mus musculus with 4 samples.

How the data were processed

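Total RNA from sorted cells of the mouse small intestine was hybridised to 4 Clariom D mouse arrays, 1 per group, per the labels' protocols. The groups are GFP-negative non-stem cells, wild-type GFP-positive stem cells, GFP-positive cells with a mutated LncGata6 and GFP-positive cells without Ehf, all from mice that carry GFP and CreERT2 under the control of Lgr5. The deposited series table holds the authors' values on the log2 scale, 1 per array feature. Affymetrix Power Tools and RMA are named in the submitters' processing notes, with versions not given in the sources used here. RMA subtracts a modelled background, equalises the arrays' distributions and summarises the probes of a feature, so differences of low features are compressed. The scale was taken from the values, which ran from -0.183 to 13.1 over the 4 arrays. Their medians were not equal, at 3.24 to 3.54 over features with 1 gene symbol, so the arrays had not been brought to an identical distribution over those features.

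The table has 72688 features, of which 65770 are transcript clusters, 5222 negative controls, 1324 positive controls and 8 labelled spike-in controls. Gene symbols came from the platform annotation supplied with the table and were updated through a RefSeq gene table of the GRCm38.p6 assembly, which changed 1432 symbols. After that, 31259 features carried 1 symbol, 1491 carried several and were left out, and 39938 were unnamed here, 33185 of them transcript clusters. This gave 30701 genes, all found in the reference gene table. For the 443 genes with more than 1 feature, the feature with the highest mean over the arrays was used. No genome build was named for the array features, so no coordinates are given.

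Each comparison is a difference of log2 values between 2 arrays. With 1 array per group no test, p-value or standard error is possible, and the number of arrays limits the precision. A gene is called higher or lower when the values differ by at least 1 (2-fold) and the brighter value lies at or above the 75th percentile of its array, which was 5.26, 4.97, 4.93 and 4.60 on the non-stem, wild-type stem, LncGata6 mutant and Ehf knockout arrays. Folds are brighter over dimmer. Where the dimmer value lay under the 95th percentile of its array's negative controls (5.16, 5.62, 5.31 and 5.19 in the same order), that percentile replaced it and the fold is given as "at least". Where the bound came to under 1, or both values lay under those percentiles, no fold is given.

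Gene lists for pathways and cell types, 31 in all, were fixed before the data were examined, as were the comparisons, the limits and most alternatives. For each list with at least 4 measured members the median difference was placed among 10000 random gene lists of the same size, matched on mean level in 20 bins. A list is called higher or lower beyond the 97.5th or 2.5th percentile, as a description of these arrays. About 1.5 of the 30 lists with a percentile fall outside by chance in each comparison. Some lists share members, such as Lgr5 and Sox9 in the stem cell and Wnt target lists, so their calls are not independent. Random lists draw genes singly, so lists of genes that vary together can exceed that rate. After the largest differences had been seen, 18 further lists of organ and blood cell genes were added, to test explanations in the closing section. The added liver, kidney, neutrophil, erythroid and T cell lists share 0 genes with the earlier lists.

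Genes are named by a rule. It takes Ehf, Gata6, Lgr4, Lgr5, Olfm4, Ascl2 and Axin2, the 10 largest differences each way among called genes, up to 4 members of each called list, and the 3 largest long noncoding differences each way. Among the 10 largest differences only, symbols of predicted genes, small RNAs, olfactory and vomeronasal receptors, antigen receptor segments and defensins were left out. Members of lists that ran against their list, members of organ and blood cell lists, and the sex-linked and leukocyte genes given with the targeted genes were chosen after their values were seen or lie outside the rule.

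Both mutant comparisons use the same wild-type stem array, which alone makes their differences correlate. Their correlation, covariance, sign agreement and overlap were therefore set beside values from 100 simulated sets of unchanged arrays with noise of 0.312 (log2 SD) on each. That SD comes from the spread of all genes between the mutant arrays, most of them at background. The spread of genes detected on either mutant array gave 0.633, which includes real differences between the mutants, and a second simulation with it was added after the data were seen. The overlap expected by chance was computed over detected genes, a choice made after the data were seen. Counting was tested on simulated arrays of 30701 genes with noise of 0.2 (log2 SD). Over the 4 comparisons, 94 to 98 of 100 genes changed by 1.5 (log2) and 97 to 100 of 100 changed by 3.0 were recovered, with 2 or 3 unchanged genes called. That noise lies under both SDs above (0.312 and 0.633), so these figures check the counting and do not measure false calls on these arrays.

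The 8 spike-in controls differed between arrays. Their mean difference was 0.47 ± 0.45 (SD over controls) for wild-type stem minus non-stem, -0.34 ± 0.42 for LncGata6 mutant minus wild-type stem and -0.85 ± 0.46 for Ehf knockout minus wild-type stem. Alternatives tried were median centring, quantile normalization and cyclic loess of the arrays, other detection and size limits, the median of a gene's features, unmatched random lists and lists without dim members. Other scalings moved the median difference of all genes by at most 0.163, 0.068, 0.206 and -0.167 (log2) in the comparisons of wild-type stem with non-stem, LncGata6 mutant with wild-type stem, Ehf knockout with wild-type stem and LncGata6 mutant with Ehf knockout. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used, with limma 3.58.1 in R 4.3.3 for the scalings.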

Results

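Gene expression was measured in sorted cells of the mouse small intestine on 4 whole-transcript arrays that read coding and long noncoding RNA. Per the labels, stem cells were sorted by GFP driven from Lgr5, the R-spondin receptor gene that marks crypt base columnar stem cells. The collection protocol of all 4 samples instead names sorting of ILCreg cells, which are innate lymphoid, so the gate used is uncertain. One array each was labelled as GFP-negative non-stem cells, wild-type GFP-positive stem cells, GFP-positive cells with a mutated LncGata6 and GFP-positive cells without Ehf. LncGata6 is a long noncoding RNA transcribed next to Gata6, and Ehf is an ETS transcription factor of epithelia. There were no replicates, so every difference is between 2 arrays and none has an estimate of its error. The comparisons address which genes distinguish stem from non-stem cells, what loss of LncGata6 or Ehf changes in stem cells, and whether both losses touch the same genes. Over 31259 named features, Pearson's r across features, which are not independent replicates, was 0.96 between the wild-type stem and LncGata6 mutant arrays, 0.92 between the wild-type stem and Ehf knockout arrays and 0.86 between the non-stem and Ehf knockout arrays.

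The targeted genes were read first. Ehf stood at 6.99 (log2) on the wild-type stem array, 5.09 on the LncGata6 mutant array, 3.03 on the Ehf knockout array and 3.75 on the non-stem array. On the array labelled Ehf knockout, Ehf and the median of 14 general epithelial genes (3.73) both lay under the control limit of 5.19, so a loss of Ehf cannot be told from the loss of epithelial transcripts. LncGata6, listed as Gata6os, read 4.92 on the wild-type stem array and 4.37 on the array labelled LncGata6 mutant, both under the control limits. Neither reading checks its label, and where the array features lie relative to the deleted parts is not known here. Its neighbour Gata6, a transcription factor of gut endoderm, read 7.21 and 7.62 on those arrays. Lgr5 itself was at 9.41 on the wild-type stem array but at 3.03 and 2.79 on the arrays labelled LncGata6 mutant and Ehf knockout, beside 3.04 on the non-stem array. Xist, expressed from the inactive X chromosome, was at 8.46 and 8.79 on the wild-type stem and Ehf knockout arrays and at 1.93 and 2.44 on the non-stem and LncGata6 mutant arrays, while the Y-linked gene Uty was at 3.39, 1.92, 5.28 and 4.50 in the same order, with only the non-stem value above its control limit. Arrays are named by their labels throughout.

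**Figure D1:**
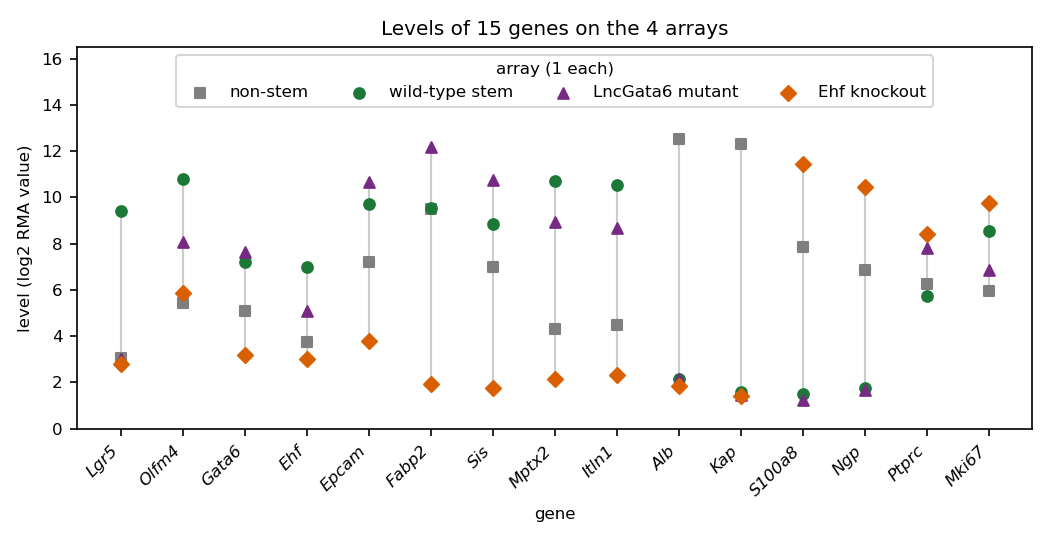
Levels (log2 RMA value) of 15 genes on the 4 arrays, 1 symbol per array, with a grey line spanning the lowest to the highest array. Lgr5 is high on the wild-type stem array at 9.41, Alb on the non-stem array at 12.5, Fabp2 on the LncGata6 mutant array at 12.2 and S100a8 on the Ehf knockout array at 11.4.

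Against the non-stem array, the wild-type stem array held more stem cell, dividing and secretory cell transcripts. Lgr5 read 9.41 against a background-level 3.04, and Olfm4, a secreted glycoprotein of crypt base stem cells, was 42.1-fold higher. Axin2, a feedback target of Wnt signalling, was at least 1.70-fold higher, Ehf at least 3.55-fold and Gata6 at least 4.14-fold. Lgr4 (difference -0.74) and the stem cell factor Ascl2 (0.82) did not pass both limits. The stem cell list had a median difference of 0.78, with 10 of 30 members higher, among them the chloride cotransporter Slc12a2 (6.71-fold) and Cdca7 (at least 1.52-fold). Its 3 lower members were Igfbp4, Fstl1 and Cyp2e1, the last a cytochrome P450 abundant in liver.

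Cell division genes were higher in 23 of 32 cases, with a median difference of 1.96, including Ccnb2 (at least 6.90-fold), Kif11 (at least 4.06-fold) and the topoisomerase Top2a (at least 5.15-fold). Paneth cell genes had the highest median difference of any list fixed beforehand, 5.45, and 9 of 10 were higher. Among them were the antimicrobial ribonuclease Ang4 (at least 28.8-fold), the lectin Itln1 (at least 41.4-fold) and the alpha-defensins Defa21 (at least 70.6-fold) and Defa22 (at least 69.9-fold), whose near-identical family may share probes. Habp2 was the lower member. Goblet cell genes (median 1.99, 10 of 15 higher) included the mucin Muc2 (8.98-fold), Agr2 (at least 25.0-fold) and Spink4 (at least 33.9-fold). Enteroendocrine genes (1.54, 10 of 23) included Chgb and the glucagon gene Gcg. Among the highest single differences were also Fabp6, an ileal bile acid binding protein (at least 16.7-fold), the pentraxins Mptx1 (at least 15.9-fold) and Mptx2 (at least 46.9-fold), the gasdermin Gsdmc4 (9.16 against a background-level 2.68) the matrix protease Mmp7 (at least 9.55-fold) and Xist (at least 9.87-fold). General epithelial genes were higher by a median of 1.97, in 12 of 14 cases, as with Epcam (5.57-fold) and the keratin Krt19 (3.71, log2). Immediate early and heat shock genes, which cell isolation can induce, were also higher, by a median of 2.25 in 14 of 16 cases, as with Fosb (at least 10.2-fold) and Hspa1a (at least 14.5-fold). The reserve stem (0.54), tuft (0.32) and innate lymphoid (0.31) lists were called higher with few members higher (2 of 8, 0 of 15 and 1 of 14), while Clu of the first and Id2 of the last were lower, by 6.48-fold and 2.68-fold. The reserve stem call ended with the median of features (0.32) and the innate lymphoid call without dim members (0.04). General epithelial genes rose more than stem cell genes and the non-stem array was rich in liver and kidney RNA, so the higher genes cannot be assigned to stem cells as such.

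The transcripts lower on the wild-type stem array were led by products of kidney and liver. Kap, an androgen-regulated protein of kidney tubules, was at least 102-fold lower, and albumin (Alb) at least 119-fold. The major urinary protein genes Mup20 and Mup3 were at least 53.2-fold and 53.6-fold lower, the pseudogene Mup-ps5 at least 60.6-fold, the fibrinogen chains Fgg and Fga at least 37.2-fold and 31.8-fold, and Apoa2 at least 71.8-fold. Fatty acid oxidation genes were lower in 13 of 15 cases (median -1.85), including Acadm (9.43-fold) and Acaa2 (8.33-fold). Enterocyte genes had a median of -1.20, with 15 of 28 lower and sucrase-isomaltase (Sis) higher by 3.62-fold. The enterocyte members that differed most, Cyp3a11 (at least 23.4-fold), Fabp1 (at least 21.7-fold), Slc2a2 (at least 6.60-fold) and Mep1a (at least 12.2-fold), are also expressed in liver or kidney. Macrophage (median -1.09), stromal (-0.86), endothelial (-0.98), interferon response (-1.22) and glycolysis (-0.82) lists were lower too, with Csf1r, Sparc, Kdr, Bst2 and Tpi1 among their members. In total 1177 genes were higher and 2171 lower on the wild-type stem array, of which 471 and 962 differed at least 4-fold. Of 30 lists, 10 were called higher and 7 lower. Quantile normalization turned the split to 1733 higher and 1683 lower.

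**Figure D2:**
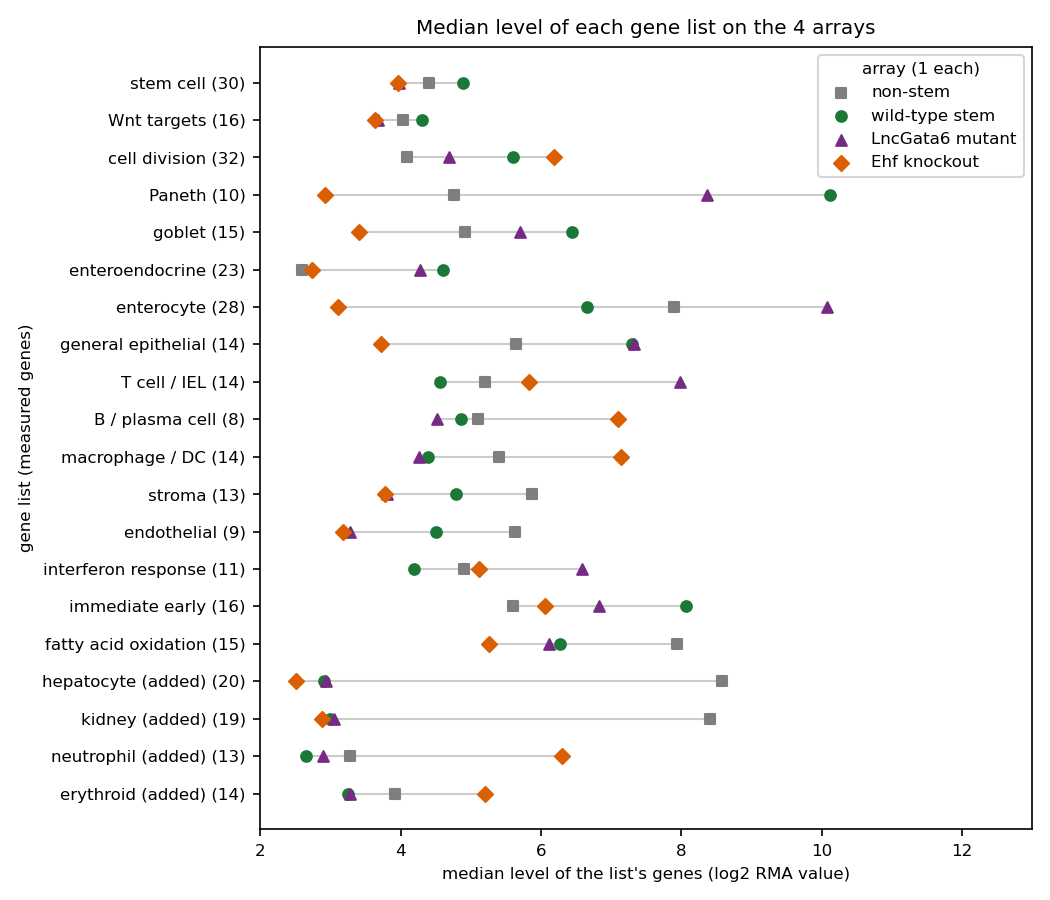
Median level (log2 RMA value) of 20 gene lists on the 4 arrays, with the number of measured genes in parentheses, 1 symbol per array and a grey line from the lowest to the highest. Lists marked as added were chosen after the largest differences had been seen. The hepatocyte list lies at 8.58 on the non-stem array and the neutrophil list at 6.29 on the Ehf knockout array, and the enterocyte list reaches 10.1 on the LncGata6 mutant array.

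On the LncGata6 mutant array, absorptive enterocyte genes stood above the wild-type stem array and stem cell genes below it. All 28 enterocyte genes were higher, with a median difference of 3.07. They included adenosine deaminase (Ada, 43.3-fold), lactase (Lct, at least 12.5-fold), the peptide transporter Slc15a1 (at least 27.1-fold) and Cyp3a11 (at least 8.23-fold). Also among the 10 highest differences were the ectonucleotidase Enpp3 (at least 35.8-fold), the sphingomyelinase Enpp7 (9.87 against a background-level 4.46), neprilysin (Mme, at least 19.4-fold), Slc5a12 (at least 3.73-fold) and Slc28a2 (at least 10.9-fold). Ly6m was at least 16.4-fold higher.

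Lgr5 was at least 17.1-fold lower, Olfm4 was 6.76-fold lower and Ehf at least 3.20-fold lower. Differences for Lgr4 (-0.95), Axin2 (-0.55) and Ascl2 (-0.83) did not pass both limits. Of 30 stem cell genes 12 were lower and 0 higher (median -1.07), including Slc12a2 (5.13-fold) and Prom1 (at least 2.57-fold). Wnt targets had a median of -0.54 with 3 of 16 lower, among them Sox9 and Cd44. Cell division genes were lower in 15 of 32 cases (median -1.04), as with Mki67 and Top2a, both 3.26-fold. All 10 Paneth genes were lower (median -1.60), including Mmp7 (4.49-fold), Ang4 (3.59-fold) and the phospholipase Pla2g2a (at least 5.36-fold). Goblet (0.13) and general epithelial (0.25) medians lay inside the range of matched random lists. Both were called higher with unmatched lists, and the goblet list also without dim members (0.22). Enteroendocrine (-0.25) and reserve stem (-0.42) lists were called lower, with 3 of 23 and 3 of 8 members lower, while the enteroendocrine gene Nts, a neurotensin precursor, was at least 6.24-fold higher.

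Transcripts of T cells and intraepithelial lymphocytes were higher in 13 of 14 cases, with a median of 3.53. Cd8a was at least 8.29-fold higher, the granzymes Gzma and Gzmb 20.1-fold and 19.1-fold, and Cd7 at least 9.36-fold. Ptprc, the pan-leukocyte CD45 gene, read 7.80 against 5.72. Interferon response genes had a median of 2.19 with 7 of 11 higher, led by Ifit1, Zbp1 and Usp18. Antimicrobial epithelial genes (0.56, 4 of 14 higher) included Duox2 and Duoxa2 (4.18-fold), which together form the epithelial hydrogen peroxide source. Endothelial (median -1.58), stromal (-0.51), immediate early (8 of 16 genes) and regenerative (-0.66) lists were lower. Vascular and stromal transcripts such as Igfbp7 (a background-level 3.93 against 8.99), Sparcl1 (at least 3.47-fold), Thbs1 (at least 5.70-fold), Apold1 (at least 3.09-fold) and tissue factor (F3, at least 2.83-fold) were among the 10 most reduced genes, as were the metallothionein Mt2 (11.2-fold) and Xist (at least 8.88-fold). In all, 862 genes were higher and 926 lower, 281 and 150 of them at least 4-fold, with 4 lists higher and 10 lower. Cyclic loess gave 1105 higher and 666 lower. The near-even split did not hold for protein-coding genes alone, of which 779 were higher and 502 lower.

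On the Ehf knockout array, epithelial transcripts of most intestinal lineages were reduced against the wild-type stem array and blood cell transcripts were raised. All 14 general epithelial genes were lower, with a median of -3.88, including Epcam (at least 22.8-fold), the cadherin Cdh1 (at least 16.6-fold) and the keratin Krt8 (at least 36.2-fold). All 10 Paneth genes were lower (median -6.30), as were 18 of 28 enterocyte genes (-2.97), 11 of 15 goblet genes (-2.28) and 10 of 23 enteroendocrine genes (-1.82). Examples are Itln1 (at least 40.5-fold), Fabp2 (at least 20.4-fold), Muc2 (at least 23.4-fold) and Reg4 (at least 12.7-fold). The most reduced genes also included the galectin Lgals2 (at least 52.6-fold), the antimicrobial lectin Reg3b (at least 54.4-fold), Mptx2 (at least 45.9-fold), Lypd8 (at least 49.0-fold) and Dmbt1 (at least 48.0-fold). Ehf was at least 3.47-fold lower and Gata6 at least 4.05-fold. Lgr4 was at least 2.51-fold lower, Lgr5 at least 18.6-fold, Axin2 at least 1.66-fold and Olfm4 31.0-fold, so the R-spondin receptors fell together with the epithelial genes. Stem cell (-0.95, 10 of 30 lower), reserve stem (-1.32, 4 of 8), Wnt target (-0.63, 3 of 16) and tuft (-0.56, 0 of 15 lower and 3 higher) lists were called lower. The tuft call ended under quantile normalization and cyclic loess, with medians of -0.21 and -0.23, and the Wnt target call without dim members (-0.55).

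The highest rises were genes of neutrophil granules and neutrophil identity. The calprotectin subunits S100a8 and S100a9 were at least 56.2-fold and 66.2-fold higher, Ngp at least 28.7-fold, lactoferrin (Ltf) at least 32.6-fold, the chitinase-like Chil3 at least 27.2-fold, the interferon-induced Ifitm6 at least 9.42-fold, Mmp8 at least 10.7-fold and Ly6g at least 7.99-fold. Macrophage and dendritic cell genes were higher in 13 of 14 cases (median 2.59), as with Tyrobp (at least 5.54-fold) and Itgam (at least 5.80-fold). B and plasma cell genes (1.87, 5 of 8) included Ighm (15.4-fold) and Ms4a1 (at least 3.91-fold). T cell genes (1.73, 10 of 14) included Ccl5 (3.79-fold), but Gzma and Gzmb were 2.41-fold and at least 1.56-fold lower. In the added T cell list 0 of 13 genes were higher and 1 was lower (Bcl11b), with a median of 0.83 at background levels. Both measured red cell genes, Alas2 and Slc4a1, were higher, at least 5.62-fold and 6.10-fold, and Ptprc was 6.44-fold higher. The interferon list had a median of 0.94 with 1 of 11 members past the limits, and the cell division list 0.23 with 3 of 32, Rrm2, Mki67 and Mcm5. Antimicrobial genes split, with Lcn2, S100a8, S100a9 and Saa3 higher and 6 of 14 lower (median -1.26). Immediate early genes (-1.78, 14 of 16 lower), endothelial (-1.29) and stromal (-0.64) genes were reduced. In all, 795 genes were higher and 1625 lower, 313 and 547 of them at least 4-fold, with 5 lists higher and 13 lower. The excess of lower genes depended on the scaling, with 954 higher and 1253 lower after median centring, 1129 and 1037 after quantile normalization, and 1099 and 1051 after cyclic loess.

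Set directly against the Ehf knockout array, the LncGata6 mutant array was higher in all 28 enterocyte genes (median 6.60), 13 of 14 general epithelial genes (3.34), 10 of 15 goblet genes (2.41) and 7 of 10 Paneth genes (4.35). Fabp2 was at least 128-fold higher, Krt20 at least 103-fold, the chloride channel regulators Clca4b and Clca4a at least 95.5-fold and 77.1-fold, Reg3b at least 89.9-fold and Sis at least 47.0-fold. Lower were S100a8 (at least 69.8-fold), S100a9 (at least 82.2-fold), Chil3 (at least 33.8-fold), Ngp (at least 35.7-fold), Ltf (at least 40.5-fold) and Mmp8 (at least 13.2-fold), with macrophage (median -2.94), B cell (-2.38) and cell division (-1.21) genes. Lgr5 differed by 0.25, with both values under the control limits. There were 1892 genes higher and 1066 lower, 802 and 401 at least 4-fold, with 9 lists higher and 3 lower, and quantile normalization gave 1418 and 1448.

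**Figure D3:**
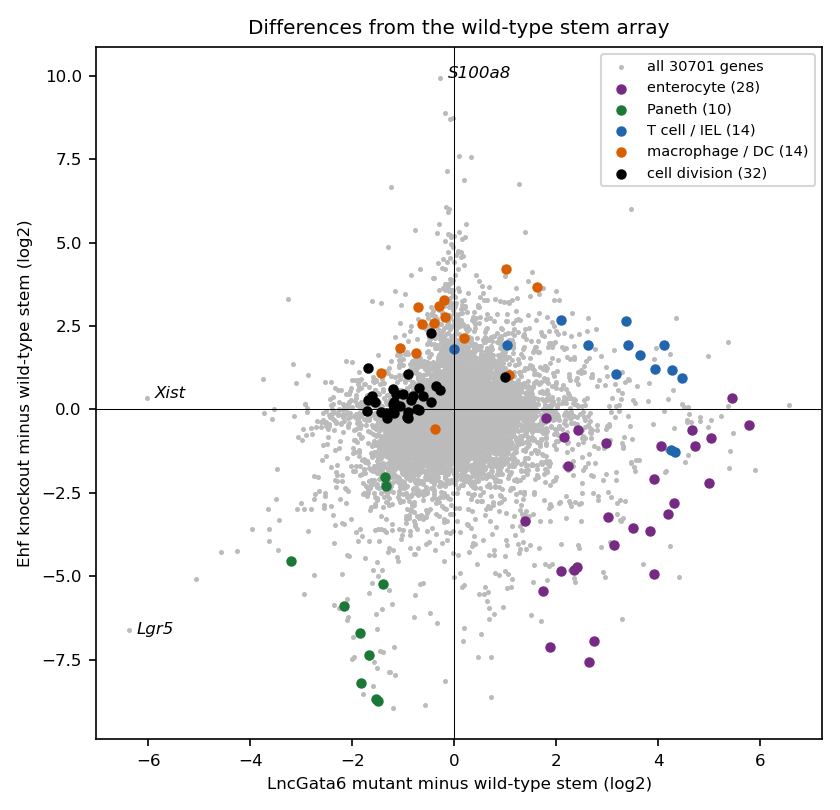
Difference from the wild-type stem array (log2) on the LncGata6 mutant array (x axis) against that on the Ehf knockout array (y axis), 1 point per gene, with the members of 5 gene lists coloured. Enterocyte genes lie to the right and mostly below 0 (medians 3.07 and -2.97), Paneth genes below 0 on both axes (-1.60 and -6.30), and Lgr5, at background on both mutant arrays, at -6.37 and -6.62.

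Both mutant arrays were lower in Lgr5, Olfm4, Slc12a2, Ehf and all 10 Paneth genes, while enterocyte genes and the granzymes Gzma and Gzmb went opposite ways. Of genes past both limits, 347 were lower on both, 106 higher on both (168 under cyclic loess) and 227 moved in opposite directions. Independent draws of these sizes from the 9636 genes detected on any of the 3 arrays would share 156 and 71.1. Unchanged arrays that share 1 control gave 18.3 lower and 15.6 higher on both with simulated noise of 0.312, the spread of all genes, but 611 and 471 with noise of 0.633, the spread of detected genes. The overlap thus lies between these values, and the shared wild-type stem array, which cannot be split, may account for it. The larger noise includes real differences between the mutants, so it can overstate what a shared control gives. In the same simulations 0 and 31.1 genes moved in opposite directions, against 227 observed, which these unchanged arrays do not reproduce. Across genes, r was 0.17 against 0.50 simulated, and the covariance was 0.082 against 0.097, a difference of -0.015. Over detected genes the covariance was 0.134, against 0.10 and 0.437 with the smaller and the larger noise, so a shared effect is neither shown nor excluded.

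Of the genes higher in wild-type stem than in non-stem cells, 83.3% on the LncGata6 mutant array and 84.3% on the Ehf knockout array were shifted toward the non-stem array, against 63.6% and 63.4% simulated with the smaller noise and 72.2% and 72.0% with the larger. Of the genes lower in stem cells, 54.5% and 39.2% were shifted toward it, against 58.0% simulated in both with the smaller noise and 62.5% and 62.6% with the larger. For these genes cyclic loess gave 62.5% and 55.0%. The LncGata6 share thus crosses the smaller-noise 58.0% but meets the larger-noise 62.5%. Cyclic loess also brought the Ehf knockout share of stem-high genes to 75.8%. No simulated value under that scaling was computed. The simulated arrays carried no offset. The median difference of all genes was -0.057 for LncGata6 mutant and -0.201 for Ehf knockout against wild-type stem. Such an offset lowers stem-high and stem-low genes alike, so the shares may partly reflect it. The non-stem array was also rich in liver and kidney RNA, which enters the stem-low genes. General epithelial genes were higher on the wild-type stem than on the non-stem array in 12 of 14 cases, and all 14 were lower on the Ehf knockout array. The shares therefore do not measure a move of stem cells toward intestinal non-stem cells.

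Among 3349 genes typed as long noncoding or antisense RNA in the RefSeq gene table, few were bright enough to be compared. The type was taken as given, also for entries named as pseudogenes such as Xlr4d-ps. In wild-type stem against non-stem cells 71 reached the limit on either array, with 9 higher and 14 lower. The highest besides Xist were Tmem238l (at least 3.46-fold) and Snhg5, a small nucleolar RNA host gene (at least 1.70-fold). On the LncGata6 mutant array 5 were higher, led by Gm5485 (at least 2.76-fold), Xlr4d-ps (both values under the control limits) and AW112010 (4.24-fold). The 4 lower ones were led by Xist, 2700038G22Rik (both values under the control limits) and Bc1 (2.80-fold). On the Ehf knockout array 7 were higher, with Gm24463 3.24-fold, and 13 lower, with Tmem238l at least 3.39-fold.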

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

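Of these alternatives, the 4-fold limit, the counts without sex-linked genes (Xist and protein-coding genes on the sex chromosomes) and the subtraction of the epithelial median were chosen only after seeing the data. Signal over background limits all values, since the arrays' medians over named features (3.24 to 3.54) lie under the 95th percentiles of their negative controls (5.16 to 5.62). Of 61 list calls 0 reversed under any alternative. A reversal needed a change of sign of the list's median, which unmatched random lists leave as it is and which the scalings could hardly reach for large medians. Median centring lost 0 and gained 0, quantile normalization lost 1 and gained 3, cyclic loess lost 1 and gained 2, the median of features lost 1 and gained 0, lists without dim members lost 2 and gained 6, and unmatched random lists lost 0 and gained 14. With unmatched lists 7 rather than 4 were higher on the LncGata6 mutant array. Of 338 named gene differences 0 reversed, but only called genes, which differ by at least 1 (log2), could count as reversed. That outcome was therefore nearly fixed in advance. Counts without sex-linked genes stayed within 1.5 times. A 1.5-fold limit gave 2109 genes higher and 3274 lower in wild-type stem against non-stem cells, 1636 and 2119 on the LncGata6 mutant array, 1275 and 3156 on the Ehf knockout array, and 2988 and 1788 between the mutants. The 4-fold limit gave 471 and 962, 281 and 150, 313 and 547, and 802 and 401. These moves follow from the limits themselves. Without a detection limit 1772 genes were higher in wild-type stem cells and 2463 lower on the Ehf knockout array. Quantile normalization left 1037 lower there and cyclic loess 1051. Ehf moved from -3.96 to -0.071 on subtraction of the epithelial median, with both at background on the Ehf knockout array, so the near-zero value shows no equality. For the shared effect, genes at or above the 75th percentile gave r 0.114, covariance 0.134 and 59.3% of the same sign. Unchanged arrays that share the control gave r 0.493 with either noise. Their same-sign shares were 66.3% with the smaller and 66.0% with the larger noise, so the observed r and share lie lower. Cyclic loess gave 168 genes higher on both. Cyclic loess also moved the share of stem-low genes shifted toward non-stem cells to 62.5% for the LncGata6 mutant. For the Ehf knockout it moved the share of stem-high genes to 75.8% and that of stem-low genes from 39.2% to 55.0%. The latter crosses 50% but stays under the 58.0% simulated with the smaller noise. The LncGata6 share crosses that value but meets the 62.5% simulated with the larger noise. With the limit at the median, 44 long noncoding genes were higher and 71 lower in wild-type stem cells, 14 higher on the LncGata6 mutant array, 24 and 54 on the Ehf knockout array, and 49 and 19 between the mutants. Except where a limit itself explains the move, the cause was not tested.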

Other observations

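All tests of the liver, kidney, blood cell, T cell, epithelial and enterocyte lists below were chosen only after the differences they address had been seen. The epithelial median on the Ehf knockout array and the enterocyte median on the LncGata6 mutant array are part of the patterns themselves. Both were known when their limits were set, so they describe the patterns and do not test them. Among ETS factors other than Ehf, Elf3, which is also expressed in epithelia, was 7.01-fold higher in wild-type stem than in non-stem cells, 2.17-fold lower on the LncGata6 mutant array and at least 7.74-fold lower on the Ehf knockout array, where Ets2 was at least 3.27-fold lower. Spi1 and Fli1, expressed in blood cells, were at least 4.26-fold and 2.64-fold higher there. The ETS list of 22 genes was inside the range of random lists in all 4 comparisons.

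Among Wnt receptors, Fzd5 was at least 2.92-fold higher in wild-type stem than in non-stem cells, while Fzd4 was at least 1.99-fold and Lrp6 2.71-fold lower. On the Ehf knockout array Fzd5 was at least 2.85-fold lower. The cell cycle inhibitor Cdkn1a, a p53 target, was 3.51-fold higher in wild-type stem than in non-stem cells and at least 7.28-fold lower on the Ehf knockout array. The p53 and apoptosis list lay inside the range of matched random lists. With unmatched lists it was called higher in wild-type stem against non-stem cells and in LncGata6 mutant against Ehf knockout. Genes of the NURF chromatin remodelling complex had medians of 0.09, -0.27, -0.12 and -0.30 in the 4 comparisons, with 1 gene past the limits in each of the first 2. Xist was high on the wild-type stem and Ehf knockout arrays and low on the other pair. The Y-linked genes Uty, Kdm5d and Eif2s3y each read higher on that other pair, though under the control limits except Uty on the non-stem array. These directions go with a difference in the sex of the mice, which was not tested. Innate lymphoid genes had medians of 0.06 on the LncGata6 mutant array and 0.01 on the Ehf knockout array against wild-type, inside the range of random lists, but 0.86 and 0.35, called higher, without dim members. Il7r and Il2rb, also expressed in T cells, were higher on both, at least 1.89-fold and 1.43-fold on the former and at least 1.37-fold and 1.38-fold on the latter. Without Xist and the protein-coding genes on the sex chromosomes 843 genes were higher and 910 lower on the LncGata6 mutant array than on the wild-type stem array.

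The non-stem array held high levels of liver and kidney genes. The added liver list had a median difference of -5.80, wild-type stem minus non-stem, and the kidney list -5.39, with Ttr at 10.9 against 3.80 and Slc34a1 at 10.4 against 3.30. RNA of both organs in the sample is a hypothesis these values fit, and 1 of 20 liver and 0 of 19 kidney genes pass detection on the wild-type stem array. Of 9 other organ lists 1 (fat cell genes) was raised by more than 1, which argues against a pool of many organs in equal shares. The medians of those lists on the non-stem array, 2.17 to 4.83, lie under its control limit of 5.16, so smaller shares could not have shown. The scalings tried moved the liver median by at most 0.206, so none of them accounts for it. Scaling by the spike-in controls was not tried. When such RNA entered, or whether another sample stands under this label, stays open, so neither genes lower nor genes higher in wild-type stem cells can be assigned to a difference between intestinal cell types.

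The Ehf knockout array held blood cell genes in place of epithelial ones. Granulocytes and erythroid cells, from blood or another source, are a hypothesis that fits, with medians of 2.87 for the neutrophil and 2.25 for the erythroid list. Ncf1 stood at 8.79 and Pglyrp1 at 8.58. The hypothesis was worded after the data were seen, so its fit is not a test. On the wild-type stem array 1 of 13 neutrophil and 1 of 14 erythroid genes pass detection, and a sort on GFP as labelled would be meant to remove such cells, but the ILCreg sort named in the protocol leaves the gate uncertain. Bone marrow as the source stays open, since the B cell precursor list moved by 0.073 but 5 of its 8 genes lie under the control limits on both arrays, while Elane (6.87) and Prtn3 (6.56), made in granulocyte precursors, were raised. The limit set beforehand would have counted that 0.073 against bone marrow. The allowance for dim genes was not part of it. The epithelial median of -3.88 describes a sample poor in epithelial transcripts, not one that stayed epithelial. As it was known when its limit was set, it tests no effect of Ehf loss. The scalings tried moved that median by at most 0.383, so none of them accounts for it. The spike-in controls differed by a mean of -0.85, also smaller in size, and scaling by them was not tried. An effect of Ehf loss on which cells entered the gate and a mislabelled sample stay open, so the differences cannot be assigned to Ehf in stem cells.

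The LncGata6 mutant array held more enterocyte and T cell transcripts and Lgr5 at background (3.03), although its cells are labelled as sorted on GFP from Lgr5. Intraepithelial T cells in the sample are a hypothesis that fits, with a median of 1.71 for the added T cell list, Itgae at 7.56 and Cd160 at 7.07, where 1 of 13 of its genes passes detection on the wild-type stem array and a sort on GFP would be meant to remove such cells, with the same doubt about the gate. The enterocyte median of 3.07 was known when its limit was set, so it does not test whether T cells are its source too. The endothelial median of -1.58 argues against a lower share of stem cells with all other types raised alike. It is a weak test, since the list's median levels (4.50 on the wild-type stem array, 3.28 on the mutant array) lie under the control limits. Of its 9 genes 4 were lower and 0 higher, with Cdh5, 6.92 on the wild-type stem array, at least 3.05-fold lower. The scalings tried moved the enterocyte median by at most 0.237, so none of them accounts for it. Scaling by the spike-in controls was not tried. Whether enterocytes entered the sort, mutant stem cells turned on enterocyte genes and lost Lgr5, or another sample stands under this label was not tested and stays open, so the differences cannot be assigned to LncGata6 in stem cells.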
